A study of Mus musculus with 19 samples.

How the data were processed

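RNA from whole mouse skin was sequenced in 19 samples, which the labels place in 4 groups by p53 allele and by the state of the gene for Aurora-A kinase in the epidermis. TopHat2 2.1.0, Partek and the mm10 build are named in the submitters' processing notes; the version of the annotation is not given in the sources used here. The table deposited by the authors lists RefSeq transcripts with a gene symbol, a chromosome and a start and end position.

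The table also has 19 columns of values, each headed by a number. None of these numbers occurs in the labels of any sample, so no column was matched to a sample or to a group by its name, and column order and the values themselves were not used for this purpose. All 19 columns were left out of every step. The comparisons planned before the data were examined, which were Aurora-A deletion within each p53 background, the p53 alleles against each other within each Aurora-A state, and the interaction, were not analysed here, and no test was run.

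Only the annotation columns were read. Among 11320 symbols with a single transcript and the start position of the RefSeq gene table for GRCm38, the assembly that mm10 names, the end was 1 base past that table's end in 9290, equal to it in 249 and at neither position in 1781. From the most frequent of these, ends are given here as 1 less than the deposited end. Starts are given as deposited and read as counted from 1, which this comparison could not test because it required equal starts. Exon numbers are those of the GENCODE M21 transcripts that GENCODE pairs with each RefSeq transcript, and overlaps are between GENCODE M21 gene spans. Listed genes were matched by symbol as written. One further item of the design is not reported here.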

Results

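RNA was sequenced from the whole skin of 19 mice that carried a tamoxifen-inducible Cre recombinase driven by the keratin 14 promoter, which is active in basal keratinocytes. The labels crossed 2 factors, the p53 genotype of the epidermis and the presence of Aurora-A, a serine/threonine kinase that acts in centrosome maturation and spindle assembly. Among mice with intact Aurora-A, 5 carried a p53 allele called gain-of-function and 5 had lost p53. Among mice in which Aurora-A was deleted in the epidermis, 4 carried the gain-of-function allele and 5 had lost p53. The p53 groups follow the genotype labels of the single samples, which give the loss group floxed p53 alleles without the knock-in mutation. The design text of the series instead writes the same p53 genotype for both groups, a floxed allele paired with a knock-in mutant allele. This conflict was not resolved here. Mice were 8 to 10 weeks old, received tamoxifen in the diet for 14 days and were treated on the skin with the phorbol ester TPA, a tumour promoter, for 7 days.

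This design asks how loss of Aurora-A changes the skin transcriptome in each p53 background, and whether the change differs between them. These comparisons were not analysed here. None of the 19 columns of expression values bears a name found in the labels, so no value was tied to a mouse or a genotype. No expression level, depth, fold change or test is therefore given for any gene, and nothing below describes a difference between genotypes.

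The annotation that accompanies the values was examined for 2 engineered genes. Aurka, which encodes Aurora-A, had 2 transcripts, NM_001291185 and NM_011497. Both lay on chromosome 2 from 172356190 to 172370570 in mm10, a span of 14381 bp, and each had 9 exons in GENCODE. Trp53, which encodes the p53 tumour suppressor, had 2 transcripts, NM_001127233 and NM_011640. Both spanned 11515 bp on chromosome 11 from 69580359 to 69591873, with 11 exons each. No other GENCODE gene overlapped Aurka or Trp53.

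The table held 35810 RefSeq transcripts under 24452 gene symbols, and 6004 symbols (24.6%) had more than 1 transcript. Of 513 genes placed before the data were examined in 34 lists of pathways and cell types, 512 had a row in the table as used here. The 27 mitosis genes, the 22 DNA replication genes and the 20 p53 targets were all present. So were the 17 genes of the list named Aurora-A partners, which also holds the related kinase genes Aurkb and Aurkc. The list of terminal differentiation genes had 24 of its 25 members, and its remaining member, Flg, which encodes filaggrin, had no row under that symbol. Several transcripts were listed for 148 of the 512 genes, among them 9 of the mitosis genes and 7 of the p53 targets.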

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

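No paired analysis was possible because no column of values was matched to a sample, and for the same reason no other normalization, filter, test or left-out mouse was tried. The planned comparisons did not pair mice either, since mice of different genotypes only share a mouse number in the labels. The alternatives for the annotation counts were chosen after seeing the data. Counting a symbol once per chromosome or scaffold gave 24534 entries against 24452, and adding synonyms from the reference table left 512 listed genes with a row. By construction neither alternative could lower its count, and only Flg was left for synonyms to match.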

Other observations

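A total of 25 gene symbols in the annotation had the form of a calendar date, covering 59 transcripts, and 2 of these symbols were on more than 1 chromosome. By their accessions, the RefSeq gene table for GRCm38 gives these 59 transcripts 27 symbols, none of them a date, which are mostly genes of the septin and MARCH families. Each of the 2 date-like symbols on more than 1 chromosome joined a pair of genes, Marchf1 with Mtarc1 and Marchf2 with Mtarc2, so the count of 24452 symbols treats each pair as 1 gene. In all, 57 symbols were on more than 1 chromosome or scaffold, so sums by symbol would join entries from different chromosomes or scaffolds. Whether such entries belong to different genes was examined only for the date-like symbols. The symbol with the most transcripts was Kcnma1, with 22.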
